A study of Mus musculus with 1 sample.

How the data were processed

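One sample was measured, parental RAW264.7 cells grown in serum-containing medium. Per the labels' protocols, total RNA was isolated with a column kit, amplified to amino allyl RNA, coupled to the dye Cy5 and handled by the protocol of the array maker, Toray. The deposited scanner output holds, per the file headers, the median pixel intensity of each spot and that of the local background around it, with no subtraction, from a scan at 3 gains. The tool that combined the gains is not given in the sources used here. The array has 27456 spots, and 0 of them carried a flag other than OK. Of these, 23474 are gene spots of 23473 probes, 2736 are blanks, 96 are negative controls, 48 are positive controls and 1102 are named No probe, whose content is not given in the sources used here.

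The authors also deposited a table of processed intensity for the same array, whose scale, centring and treatment of low values the labels do not state. Set against the scanner values, its 16689 whole numbers follow the spot median minus the trimmed mean of the blanks, scaled by about 0.486. That factor is the mean over the 2987 probes with values over 200 (SD 0.000364). The median of the table is 25 and its maximum is 24556. Spearman's rho across probes was 0.9996, and probes are not independent replicates. Its 6784 empty cells are the probes whose signal was 22.97 or lower, which is the blank limit used here up to 1 probe. The scale and the treatment of low values were thus found from the values, the values are linear intensities with no direction, and why the median was set to 25 stays unknown.

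A gene probe was called over the blank limit where its signal exceeded the mean plus 2 SD of the blanks after 5% of them were left out at each end. The 2464 blanks used had a mean of 20.6 and an SD of 1.18, which gave 22.98. The receptor limit is the 95th percentile of the 1221 olfactory, vomeronasal and taste receptor probes, 55.8 or 2.43 times the blank limit. It was listed as an alternative before the data were examined, and its use as a second reported limit was chosen afterwards. Signals are spot medians with no local background subtracted, and spots of a probe present more than once were averaged. A gene takes its highest probe, and probes of a named gene are given apart where they fall on different sides of either limit. Of 1283 genes with several probes, 377 had probes that disagreed on the blank limit, and the median ratio of highest to lowest probe was 1.89. Signal also depends on the probe, so single genes were not ranked against each other. A low reading can come from a poor probe as well as from a scarce transcript.

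Gene names came from the platform's probe annotation, with symbols updated through gene identifiers to a RefSeq gene table of mouse assembly GRCm38.p6, used for names only. One symbol was given for 20690 probes, several for 0 and none for 2783, and 20556 matched the gene table. No build is named for the probes, and no coordinates are given.

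The gene lists, 37 in all, of which 33 are lists of symbols and 4 are family patterns, were fixed before the data were examined. They cover peroxiredoxins and peroxide metabolism, scavenger and Toll-like receptors, Maf factors, internalisation, macrophage states, inflammation, growth and metabolism, markers of 11 other groups of cell types, sex-linked genes and receptor families. The genes named in the text were fixed as 37 symbols, of which 34 had a named probe and 3 had none, plus up to 6 members of each list that were not over the blank limit, first in alphabetical order. For each list of another cell type the rule adds up to 6 members over the limit, again in alphabetical order. The text prints only part of the members this rule takes, mainly for the other cell types, and that part was picked after the values were seen. Other genes named in the text, and 7 further lists given among the other observations, were chosen after the data were examined; the iron list was drawn up after the signals of the ferritin genes had been seen.

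For each list the share of genes over a limit is given with its exact Clopper-Pearson 95% interval, which treats genes as draws and covers no difference between arrays. The list's median log2 signal was placed among the medians of 10000 random lists of the same size from the named genes, which does set levels of different probes side by side, describes this array and is no test. With 1 array there is no spread between samples, and the comparison of parental with mutant lines was not made.

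Alternatives listed before the data were examined were 1 or 3 SD in place of 2, the 99th percentile of the blanks, no trimming, the receptor limit, the authors' table, normexp background correction with an offset of 50, calls that need all probes of a gene, its lowest probe, and medians over detected genes. Leaving out spots with a bad flag was listed too and not run, because there were 0 such spots. Further limits, and runs of the named genes under more of the limits, were added after the data were examined. The text reports what the alternatives did to the count of probes over the limit and to the shares of peroxiredoxins, macrophage identity, scavenger receptors, clathrin and caveolar genes, chemosensory receptors and other cell types, a choice made after the list values had been seen.

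The procedure was tested on simulated data. In simulated spots with the spread of the blanks, 6.64% of 5000 dim spots passed the blank limit, as did 87.3% of spots at 1.1 times the limit and 100% at 1.5 times. The dim spots were drawn with the blanks' own mean and spread, so this is no false call rate for gene probes. The receptor limit was not simulated. Of 300 simulated lists of 25 genes with no shift, 8.67% fell outside the 5th to 95th percentiles, and 98.7% of 300 lists raised 4-fold lay over the 95th. The list simulations drew on the 19321 genes of the array, as did the random lists they were placed among. The share with no shift was thus set by construction, and lists of related genes or of other sizes were not simulated. Positive control spots repeated 24 times across the array had a coefficient of variation of 4.98% in the set with a mean of 12934 and 5.37% in the set with a mean of 29508. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.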

Results

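RAW264.7 is a mouse line that behaves like a macrophage in culture. It takes up added peroxiredoxin, an enzyme that breaks down peroxides inside cells and acts as an alarm signal outside them. The study asked which genes this uptake needs. Its design sets parental cells against lines made with the alkylating mutagen ENU and sorted for loss of uptake. The data used here are 1 one-colour array of the parental line, and mutant arrays were not analysed here, so no line was compared with another. The sections that follow give which genes and gene groups gave signal in the parental cells. There are no replicates, the number of arrays limits the precision of every value, and no p-value is given. Genes named beyond those fixed in advance were chosen as examples after their values were seen.

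The array read 23473 gene probes, which name 19321 genes, and the median gene signal was 36.2 arbitrary units in a range from 16.2 to 50569. Over the blank limit of 22.98 lay 14070 genes, or 72.8% (exact Clopper-Pearson 95% interval 72.2 to 73.4). Receptors of smell and taste, the olfactory, vomeronasal and taste receptor families, gave a check of that limit, because a macrophage line has no known use for most of them. Of 1210 such genes, 451 also passed it, or 37.3% (34.5 to 40.1). Counts are therefore given at a higher limit too, the 95th percentile of the probes of these receptors, which was 55.8 and is called the receptor limit. Reporting it beside the blank limit was chosen after this share was seen. At the receptor limit, 8258 genes passed, or 42.7% (42.0 to 43.4). The intervals cover the counting of genes only.

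**Figure D1:**
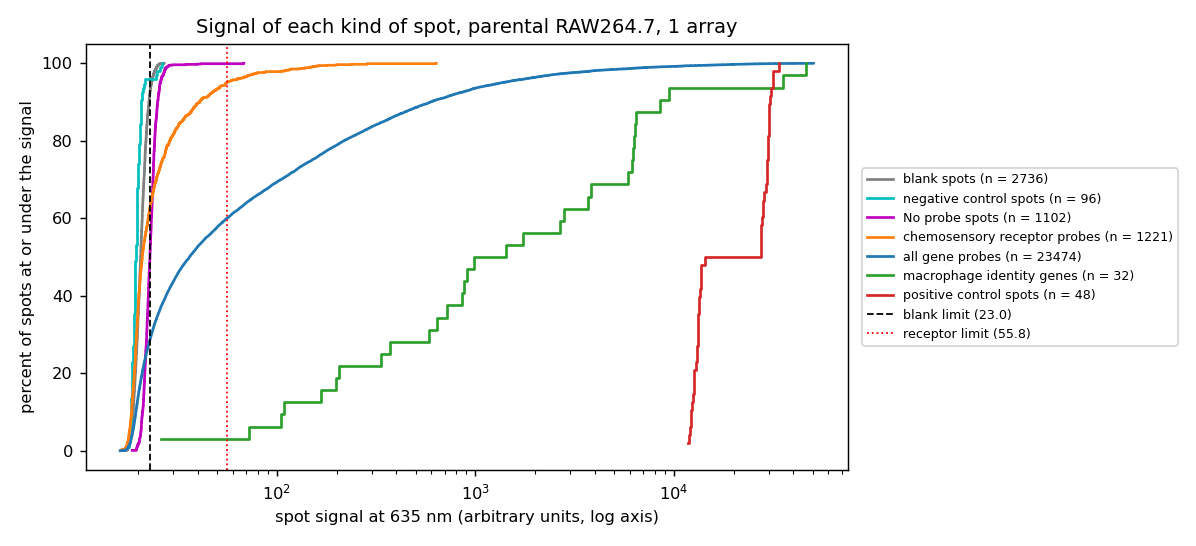
The plot gives the percent of spots (vertical axis) at or under each signal in the Cy5 channel in arbitrary units (log axis) for each kind of spot on the array, with the macrophage identity genes drawn at their highest probe and both limits as vertical lines. Blank spots have a median of 20.6, positive controls lie over 11723, and all but 1 of the 32 macrophage genes lie over the receptor limit of 55.8.

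Genes of macrophage identity gave signal almost without exception. All 32 measured members passed the blank limit and 31 passed the receptor limit, which is 96.9% (83.8 to 99.9). Spi1 (probe M300000282), the transcription factor PU.1 of myeloid cells, read 858, and Csf1r (probe M300004245), the receptor for the macrophage growth factor CSF-1, read 642. The surface marker Adgre1, known as F4/80, read 205, the integrin chain Itgam read 109, and the lysosomal glycoprotein Cd68 read 6442. The lysozyme gene Lyz2 read 46513 and its near-identical paralog Lyz1 read 35455, and the signal of each is uncertain because transcripts so alike can bind either probe. Csf2rb, a chain of the GM-CSF receptor, was the member between both limits, at 26.1. The median of the list, 1205, lay at the 100th percentile of the medians of 10000 random lists of the same size.

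Peroxiredoxins, the proteins whose uptake the study concerns, were also made by the line at the transcript level. The 4 members with a named probe all passed both limits. Prdx1 (probe M300006233) read 17714, or 771 times the blank limit. Prdx2 (probe M200013971) read 2316, mitochondrial Prdx3 (probe M200006674) read 2430, and Prdx4 of the endoplasmic reticulum (probe M200003736) read 1873. The list of thioredoxin and peroxide genes also holds superoxide dismutases and regulators of the oxidative stress response such as Nfe2l2. Of its 23 genes, 22 passed the blank limit and 20 passed the receptor limit, with a list median of 663. Txnrd1, the cytosolic thioredoxin reductase, read 2039, and probes of Srxn1, the sulfiredoxin that repairs overoxidised peroxiredoxin, read 663 and 236. The cytosolic thioredoxin Txn1 lay between the limits at 45.6, as did Nqo1 at 26.8, and Sesn3, a sestrin, was not over the blank limit at 20.4. Whether poor probes lowered these readings was not tested.

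Scavenger receptors, which bind modified lipoproteins and released cell proteins, ranged from clear signal to none over the blanks. Of 23 measured, 18 passed the blank limit, or 78.3% (56.3 to 92.5), and 10 passed the receptor limit, or 43.5% (23.2 to 65.5), which leaves 8 between the limits. Msr1 (probe M300004444), the class A scavenger receptor, read 612. Cd36 (probe M300000349), a class B receptor for oxidised lipids, read 1024, and Cd14 (probe M200001343), a co-receptor for bacterial lipopolysaccharide, read 6216. Clec7a, the beta-glucan receptor dectin-1, read 599, Lrp1 read 252 and the HDL receptor Scarb1 read 152. Stab1 lay between the limits at 31.7. Not over the blank limit were Marco (probe M400000921) at 22.6, which did pass the limit of its own block at 1.03 times, the hemoglobin receptor Cd163 at 20.3, the mannose receptor Mrc1 at 19.9, Megf10 at 19.6 and Vldlr at 19.2. The list median, 34.7, lay at percentile 34.9 of random lists, and at percentile 95.1 when list and random lists held only genes over the blank limit.

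Maf transcription factors and their partners, which include regulators of macrophage genes and of the oxidative stress response, lay near the middle of all genes. The list median, 41.8, was at percentile 52.9 of random lists, and at 17.75 among genes over the blank limit only. Of 11 measured, 9 passed the blank limit and 3 passed the receptor limit. These 3 were Nfe2l2, which encodes the stress regulator NRF2, at 706, the small Maf gene Mafg at 269, and Nfe2l1 at 213. Maf itself (probe M400005175) lay between the limits at 26.4. The erythroid factor Nfe2, at 19.0, and the retinal factor Nrl, at 19.4, were not over the blank limit.

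Among genes of internalisation, the lysosome and phagocytosis lists passed the receptor limit at shares whose intervals lay over the 42.7% of all genes, and the interval of the clathrin list held it. In the clathrin and caveolar list, 26 of 29 genes passed the blank limit, or 89.7% (72.6 to 97.8), and 18 passed the receptor limit, or 62.1% (42.3 to 79.3). The clathrin light chain Clta read 5889 and the adaptor subunit Ap2s1 read 2808, while 1 probe of the heavy chain Cltc read 3179 and its other probe read 30.1. The caveolin genes Cav1, Cav2 and Cav3 lay between the limits at 34.9, 52.8 and 24.0, and the caveolar coat gene Cavin1 was not over the blank limit at 21.7. The dynamins Dnm2, at 22.7, and Dnm3, at 19.1, were not over it either, though Dnm2 passed the limit set from the negative controls, 22.6. Whether these low readings come from missing transcripts or from probes that do not respond was not tested. Of 29 genes of phagocytosis and macropinocytosis, 26 passed the blank limit and 22 the receptor limit, or 75.9% (56.5 to 89.7), among them Arpc2 of the actin-branching complex at 10648 and the Fc receptor chain Fcer1g at 9468. The engulfment genes Gulp1, Timd4 and Tyro3, at 19.9, 20.4 and 20.1, did not pass. All 28 endosome and lysosome genes passed the blank limit and 25 the receptor limit, or 89.3% (71.8 to 97.7). The protease Ctsb read 7869 and the membrane protein Lamp1 read 5775, and the list median was 1183.

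Of 21 Toll-like receptors and adaptors, genes of innate sensing, 19 passed the blank limit and 14 the receptor limit, or 66.7% (43.0 to 85.4). Tlr2, the receptor for bacterial lipoproteins, read 1917, the adaptor Myd88 read 926 and the lipopolysaccharide receptor Tlr4 read 110, whereas Tlr5 at 19.9 and Tlr11 at 20.7 were not over the blank limit. In the inflammasome list, 12 of 14 passed the blank limit and 8 the receptor limit. The sensor Nlrp3 read 106 and the protease gene Casp1 read 838. With normexp, Nlrp3 lay at 1.09 times the limit of that setting and Casp1 at 9.42 times. Pycard (probe M200004810), which encodes the adaptor ASC that RAW264.7 cells are known to lack, read 22.4 and was not over the blank limit on its 1 named probe, although it passed the limit of its own block at 1.001 times. Mefv, at 20.9, was not over the blank limit either.

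Cytokine and chemokine genes passed at shares whose intervals hold those of all genes, 72.8% and 42.7%. Of 30 cytokine and chemokine genes, 21 passed the blank limit, or 70.0% (50.6 to 85.3), and 11 passed the receptor limit, or 36.7% (19.9 to 56.1). The chemokines Ccl9 and Ccl3 read 3606 and 3142, and Tnf read 385. Il1b lay between the limits at 45.1. The growth factors Csf2 and Csf3, the chemokines Ccl7, Ccl12 and Cxcl1, and the IL-12 chain Il12a read from 17.6 to 20.7 and did not pass, nor did Il6 at 18.5 and Nos2, the inducible nitric oxide synthase, at 19.5. Interferon-stimulated genes passed the blank limit in 19 of 21 cases and the receptor limit in 11. Ifitm3 read 4827 and Oas1a read 336, while Ifit1 at 20.4 and Ifit3 at 20.8 did not pass.

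**Figure D2:**
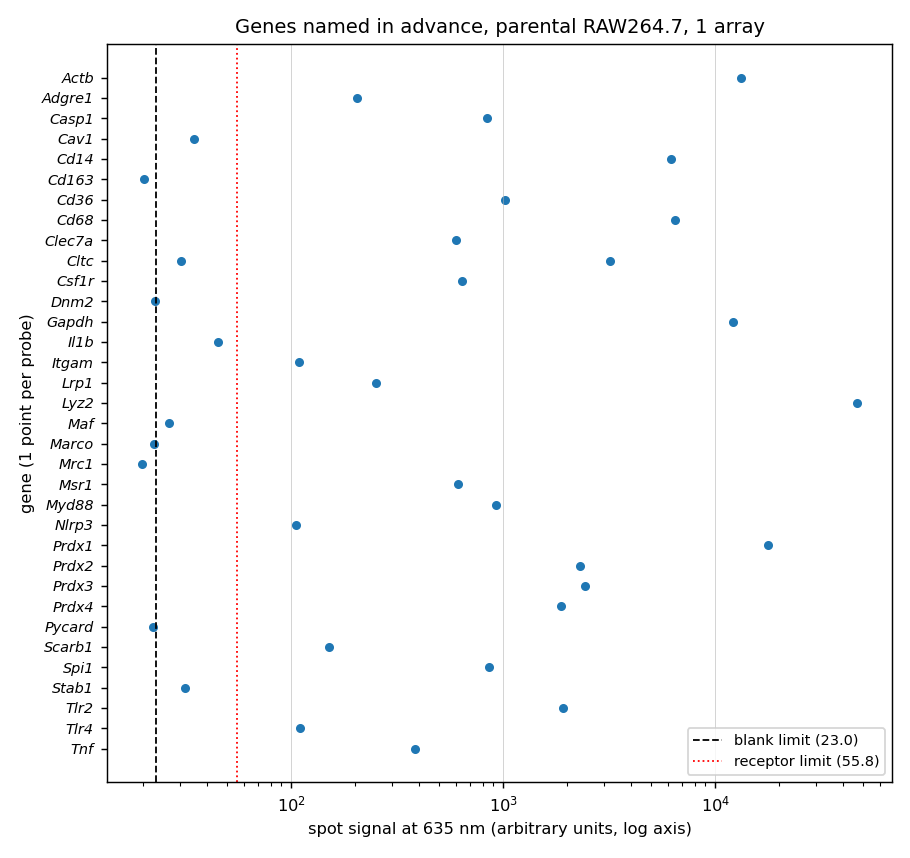
Each point is 1 probe of a gene fixed in advance, placed by its signal in the Cy5 channel in arbitrary units (log axis) on the single parental array, with the blank limit of 22.98 and the receptor limit of 55.8 as vertical lines. Msr1 at 612 and Prdx1 at 17714 lie to the right of both lines, and Marco, Mrc1, Cd163, Dnm2 and Pycard lie left of the blank limit of the whole array.

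Of the lists of specialised macrophage states, the tissue-resident list had an interval under the 42.7% of all genes at the receptor limit, and the other intervals held the shares of all genes at both limits. Of 15 genes of alternative activation, the state induced by interleukin-4, 9 passed the blank limit and 6 the receptor limit, or 40.0% (16.3 to 67.7). The interleukin-4 receptor chain Il4ra read 206, while Arg1 at 18.7, Chil3 at 17.6, Retnla at 21.9 and Pparg at 19.1 were not over the blank limit. Of 18 genes of tissue-resident macrophages, 10 passed the blank limit and 2 the receptor limit, or 11.1% (1.38 to 34.7), namely the chemokine receptor Cx3cr1 at 1374 and Nr1h3 at 61.1. The complement gene C1qa read 21.7, the Kupffer cell gene Clec4f 22.9, the microglial genes P2ry12 and Sall1 20.5 and 19.6, the alveolar macrophage gene Siglecf 20.4 and the red pulp factor Spic 20.5. That list's median, 25.1, lay at percentile 5.76 of random lists, and between 1.93 and 8.66 in the other settings run. RAW264.7 cells can form osteoclasts, and of 15 osteoclast precursor genes 13 passed the blank limit and 9 the receptor limit, or 60.0% (32.3 to 83.7). Among them 1 Mitf probe read 1037 and the other 54.8, between the limits, and Nfatc1 read 115, while the mature osteoclast proteases Ctsk and Mmp9 read 20.4 and 18.8 and did not pass.

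Genes of growth and basic metabolism passed both limits nearly throughout. All 31 cell cycle genes passed the blank limit and 29 the receptor limit, with the replication clamp Pcna at 11015 and the mitotic kinase gene Cdk1 at 3477. The 2 between the limits were Ccnd2 at 29.5 and Myc at 40.6. All 17 DNA repair genes passed the blank limit and 15 the receptor limit, among them the abasic site nuclease Apex1 at 2376. The 15 glycolysis genes passed both, with Ldha at 14684 and Gapdh at 12099, and so did the 25 proteasome genes, whose median was 2829. Of 20 listed ribosomal proteins, 20 passed the blank limit and 19 the receptor limit, with a median of 19699. In the wider ribosomal protein family 64 of 66 genes passed the blank limit and 59 the receptor limit. The 2 that did not pass were Rpl10l, a copy used in testis, at 22.9 and Rpl3l, a copy used in muscle, at 18.8. Actb, cytoplasmic actin, read 13247.

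Markers of other cell types were sparse at the receptor limit. Over the 11 lists of such markers, 83 of 163 genes passed the blank limit, or 50.9% (43.0 to 58.8), and 19 passed the receptor limit, or 11.7% (7.17 to 17.6). Of 19 T and NK cell genes, 9 passed the blank limit and 1 the receptor limit. The CD3 chains Cd3d, Cd3e and Cd3g read 30.5, 20.1 and 21.6, and Cd4, Cd5, Cd8a and Cd28 lay between the limits at 27.2 to 35.7. The gene over the receptor limit was Foxp3 at 350, whose other probe read 22.6. Of 14 B cell genes, 8 passed the blank limit and 3 the receptor limit, with Blnk at 1276 and Pax5 at 19.6. Binding of other transcripts to the marker probes was not checked. The 19 granulocyte and mast cell genes had 12 and 4 passing, with Mpo at 18.6, S100a9 at 19.4 and Csf3r at 105. The 10 erythroid and platelet genes had 5 and 0 passing.

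Outside blood, 8 of 13 fibroblast genes passed the blank limit and 1 the receptor limit, with Col1a1 at 26.6. Of 12 endothelial genes, 5 and 2 passed, with Pecam1 at 19.4 and Flt1 at 387. Of 14 epithelial genes, 7 and 1 passed, with Epcam at 22.3 and Cldn4 at 249. Among 19 neuron and glia genes, 10 and 1 passed, and 8 and 2 among 14 hepatocyte genes, where Ttr read 19.4 and Fgb read 176. Muscle gave 4 and 1 of 14, and germ cells 7 and 3 of 15, with Prm1 at 17.7 and Ddx4 at 190. In the olfactory family 399 of 1014 genes passed the blank limit and 53 the receptor limit, and in the vomeronasal and taste families 52 and 8 of 196. The joint share of these families over the receptor limit was set by the construction of that limit and is no result. Keratin-associated proteins and beta-defensins, products of hair and epithelia, had 37 and 9 of 70.

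RAW264.7 was derived from a male mouse. Of 5 Y-linked genes measured, 2 passed both limits, namely Eif2s3y at 557 and Kdm5d at 64.4. Sry, the testis-determining gene, read 20.3, Usp9y read 21.4 and Zfy1 read 21.6. The 1 gene of X inactivation, Xist, lay between the limits on both of its probes, at 31.5 and 38.0.

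**Figure D3:**
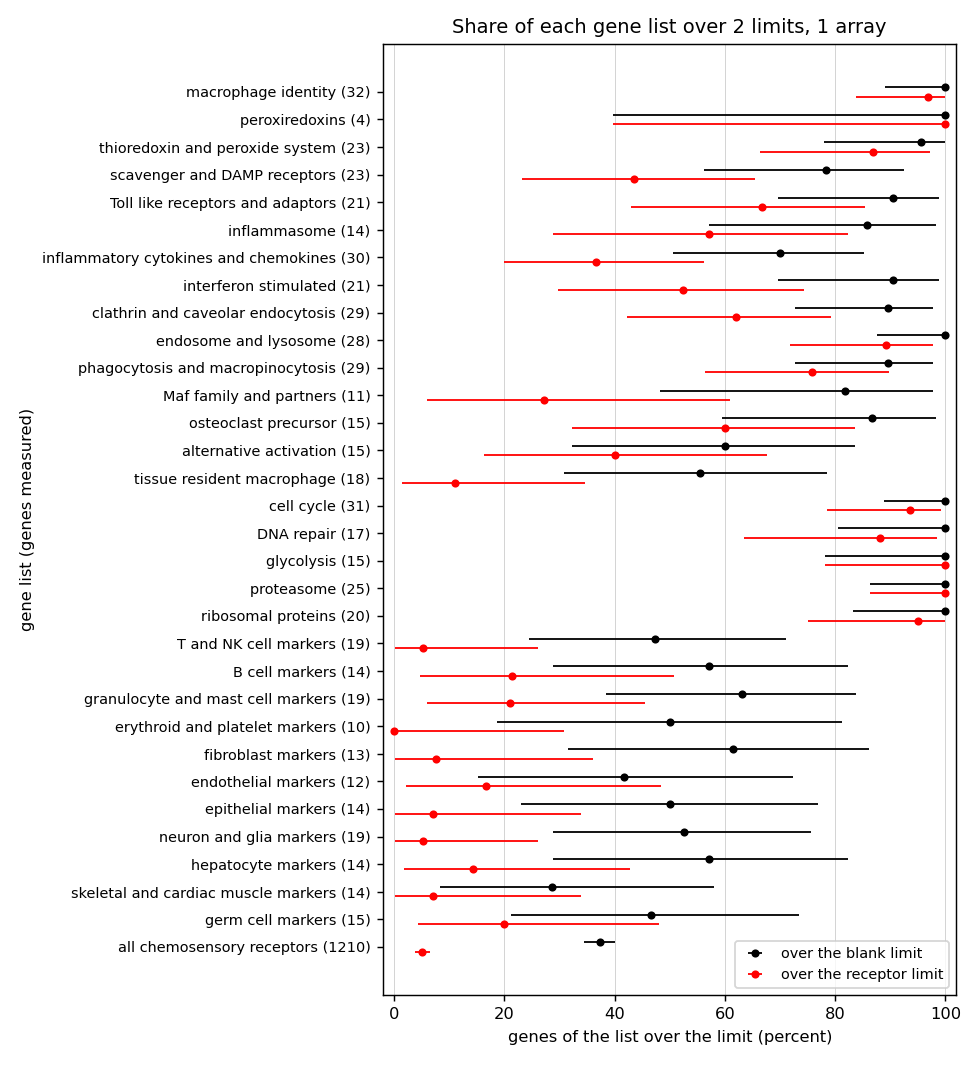
Points give the percent of measured genes of each list (number in brackets) over the blank limit (black) and over the receptor limit (red) on the single parental array, and bars are exact 95% intervals that cover the counting of genes only. Macrophage identity stands at 100% and 96.9%, scavenger receptors at 78.3% and 43.5%, and chemosensory receptors at 37.3% and 5.04%, the last set by the construction of the receptor limit.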

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

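The 2 counts in this part concern spots outside the gene lists and were taken after the data had been examined, and so was the check of the first with block limits, the only one made. Among the 1102 spots named No probe, 531 lay over the blank limit, or 48.2% (exact 95% interval 45.2 to 51.2), against 4 of the 96 negative controls, or 4.17% (1.15 to 10.3). What these spots carry is not given in the sources used here, so the negative controls are no matched control for them. Their median was 22.9 and the highest read 68.1. All of them lie in row 10 of their blocks. With the limit set from the blanks of each spot's own block the share did not fall, at 55.7% (52.7 to 58.7).

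Of 2783 gene probes without a gene symbol, 866 lay over the receptor limit, or 31.1% (29.4 to 32.9), against 41.3% (40.6 to 41.9) of the 20690 probes with a symbol. Which transcripts the 866 probes read was not analysed here.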

How the results depend on the processing

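The limits from the No probe spots, the negative controls, each block and any value in the authors' table were chosen after the data had been seen, and so were the results printed in this part and the runs of named genes under these limits, 1 SD, the 99th percentile and no trimming. The receptor limit lowered the probes called from 16688 to 9403, scavenger receptors from 78.3% to 43.5%, clathrin and caveolar genes from 89.7% to 62.1%, other cell type markers from 50.9% to 11.7%, and chemosensory receptors from 37.3% to 5.04%, the last by its construction. Under other settings, chemosensory receptors stood at 31.9% with 3 SD, 44.0% with 1 SD, 29.8% with the 99th percentile of the blanks, 34.2% without trimming, 33.8% with values above the minimum of the authors' table, 24.96% with normexp and 26.9% with the 95th percentile of the No probe spots. Other cell type markers stood at 60.1% with 1 SD, 40.5% with the 99th percentile, 35.0% with normexp and 38.7% with the No probe limit. Higher limits call fewer genes by their construction; the cause of the normexp shift was not tested. Peroxiredoxins stayed at 100%, which is 4 genes with an interval of 39.8 to 100, and macrophage identity at 96.9% or more in every setting run. Over the 39 fixed lists and combinations of them, 25 shares left the exact 95% interval of their main value under the receptor limit, all downward, and at most 6 did under any other setting. These intervals are wide for short lists: endothelial markers went from 41.7% to 16.7%, osteoclast genes from 86.7% to 60.0% and alternative activation from 60.0% to 40.0% under the receptor limit, and scavenger receptors to 56.5% under normexp, all inside them. Among 34 named genes, Cav1, Il1b, Maf and Stab1 lost their call under the receptor limit, and Maf and Stab1 under normexp. Dnm2, Marco and Pycard gained a call with 1 SD (1.04, 1.04 and 1.03 times that limit), Marco and Pycard with the limit of their block (1.03 and 1.001 times) and Dnm2 with the negative controls (1.002 times). Of the percentiles of 36 list medians, 25 left the sampling error of the random lists with detected genes only, 27 with the lowest probe, 25 with normexp and 14 with the authors' table. The largest shifts were 63.5 points for Y-linked genes with detected genes only (median shift 3.69), 9.45 for scavenger receptors with the lowest probe (1.44), 21.5 for cytokines with normexp (1.72) and 3.13 for granulocyte markers with the authors' table (0.217). Signal over background sets the limit for genes between 22.98 and 55.8, where receptors of smell and taste also lie. With 1 array no replicate could be left out.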

Other observations

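Of the tests in this part, only the one with block limits was written down before its result was seen; the others, and the 7 gene lists described first, were chosen after the data had been examined. The parental cells gave signal for antigen presentation genes. All 12 genes of MHC class I and peptide loading passed the blank limit and 10 passed the receptor limit, or 83.3% (51.6 to 97.9), against 42.7% of all genes. The light chain B2m read 4327 and H2-K1 read 2486, while H2-D1 lay between the limits at 23.6. All 12 class II genes passed the blank limit and 8 the receptor limit, or 66.7% (34.9 to 90.1), an interval that holds the 42.7% of all genes. The invariant chain Cd74 read 896 and H2-Aa read 195. Chemokine and purinergic receptors passed in 14 of 20 cases at the blank limit and 6 at the receptor limit. Ccr4, known best from T cells, read 2246, Cx3cr1 read 1374 and the UDP receptor P2ry6 read 418, whereas Ccr1 at 18.8 and Ccr7 at 20.4 did not pass.

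Most measured genes of the lists of cholesterol synthesis, ATP synthase and cytochrome oxidase, and iron passed both limits. Of 18 cholesterol synthesis genes, 17 passed both limits, with Sqle at 1053 and Msmo1 at 1496, and Pmvk read 18.9. All 23 genes of ATP synthase and cytochrome oxidase passed both limits, with a median of 7197. Iron genes passed in 12 of 14 cases at the blank limit and 11 at the receptor limit. The ferritin chain Fth1 read 39759 and the probes of Ftl1 read 39633 and 26088, the lysosomal metal transporter Slc11a1 read 523, and the hepatic hormone gene Hamp read 19.5. Of 37 HOX genes, 23 passed the blank limit and 9 the receptor limit, with Hoxb7 at 665 and Hoxa7 at 218, and the list median, 25.6, lay at the 2.07th percentile of random lists.

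Receptors of smell and taste passed the blank limit at 37.0% of their 1221 probes (34.3 to 39.8). A background gradient between blocks is argued against, since with the limit of each probe's own block the share was 38.7% (35.9 to 41.5). Background around single spots may add a part and stays open: normexp, which uses it, gave 24.96% of these genes in place of 37.3%. Across all gene spots, Spearman's rho of signal with local background was 0.879, and 1564 spots read under their local background. Neither value was computed for these receptors alone. The rho decides nothing, since it cannot tell background that adds to a spot from light that a spot sheds around itself. Light from neighbouring spots stays open too, since with the spots left, right, above and below all under the limit the share was 23.9%, but that is 11 of 46 probes, with an interval of 12.6 to 38.8, and judging it by the interval was decided after the share had been seen. Nonspecific binding is also open, because the negative controls passed at 4.17% but their sequences are not given in the sources used here, and no biological explanation was tested.

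Among the markers of other cell types, 19 passed the receptor limit, among them Blnk at 1276, Flt1 at 387, Foxp3 at 350, Cldn4 at 249 and Ddx4 at 190. Cells of types other than granulocytes stay open: the highest median of such a list, 26.4, lies under the limit of 55.8, but this follows from the counts and decides nothing, and of hepatocyte genes Fgb at 176 and G6pc at 79.3 passed while Alb at 23.9, Ttr at 19.4 and Apoa2 at 21.5 did not. Granulocytes stay open as well, since of 5 of their abundant transcripts 1 passed, S100a8 at 60.2, while Ltf read 27.5, Ngp 23.9, Camp 22.4 and S100a9 19.4, and Ly6g, at 66.7, passed as well. Signal of single probes could account for part of the group, since the 3 of these genes with several probes each had another probe under the blank limit (Ebf1 56.4 against 22.4 and 22.0, Foxp3 350 against 22.6, Mog 146 against 18.5). On the whole array this held for 129 of 711 such genes, or 18.1% (15.4 to 21.2). Those genes were not matched for signal, and Ebf1 lay just over the limit of 55.8, so the contrast is not between like genes. The other 16 marker genes have 1 probe and no such check. Transcript variants, binding of other transcripts to these probes, which was not checked because probe sequences were not used here, and true expression of Blnk, Flt1 and Csf3r, which are also known from myeloid cells, all stay open.

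Pycard, at 22.4, was not over the blank limit, but it passed the limit with 1 SD at 1.03 times and that of its own block at 1.001 times. Nlrp3 and Casp1, whose products act with that of Pycard, read 106 and 838. With normexp, Nlrp3 lay at only 1.09 times the limit of that setting, and Casp1 at 9.42 times. A probe that does not respond could give the same reading for Pycard, and with 1 named Pycard probe on the array this cannot be told apart from a missing transcript. The lack of this adaptor known for RAW264.7 was not tested here by any other measure.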
